A study of Arabidopsis thaliana with 7 samples.

How the data were processed

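RNA from guard cell protoplasts was hybridised to 7 one-colour Agilent arrays, 4 of Me-0 and 3 of tetraploid Col. Per the labels' protocols, plants grew for 18 days on solid medium under constant white light of 80 μmol per square metre and second at 22 °C and 60% relative humidity, were moved to pots, and gave protoplasts from rosette leaves at 4 weeks of age; 100 ng of total RNA was amplified and labelled with Cy3. The labels number the replicates but do not say that they came from separate plantings or isolations, so p-values measure only the spread between these samples, which may be technical.

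Each array file held spot intensity values: per the file headers, the authors ran Agilent Feature Extraction, version 10.7.3.1 for the Me-0 arrays and version 11.5.1.1 for the tetraploid Col arrays, which gave a processed signal after background subtraction, median foreground and background intensities, and flags. The other deposited columns used here were those flags, for outlier spots and for signal over background. The authors also deposited a series table of signal values; its 7 columns held identical sorted values with a median of 1.00 each, as quantile normalization gives, and followed the processed signal (Spearman's rho at least 0.998 on each array). The scale of that table is linear, and the factor that sets its median is not given in the sources used here. Per the file headers, all 4 Me-0 arrays lay on 1 slide read by one scanner model in 1 pass, and all 3 tetraploid Col arrays on another slide read by another model in 2 passes. Each group therefore lay in a batch of its own, and batch and group cannot be told apart.

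From the deposited files, the log2 processed signal minus the array's 75th percentile over 43603 non-control probes was computed. Control spots and outlier-flagged spots (3 to 23 per array) were left out and spots of a probe were averaged. No spot was saturated (0 on each array). Negative control spots had a median signal of 14 to 15 on the Me-0 arrays and 52 to 56 on the tetraploid Col arrays. Probes are 60 bases long. RefSeq accessions paired 34222 probes with 1 locus of the TAIR10.1 gene table, locus names in the files gave 1425 more, 475 matched several loci and 7481 matched none; the last 2 kinds are in no gene count. Probes were kept if well above background on every array of at least 1 group, which left 32230. For a gene with several probes, the probe with the highest mean normalized signal over the 7 arrays was used. Well above background were 71.4% to 75.3% of probes per array, and the number of arrays limits the precision.

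Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over 20216 genes; a gene was called higher or lower at an adjusted p below 0.05 and an absolute log2 difference of at least 1. Every difference is Me-0 minus tetraploid Col, every ± is an SD unless marked SE, and every adjusted p of a gene is limma's. A gene whose probe was not well above background on any array of a group has a bound only: the bright group's mean against the dim group's mean of, per array, the higher of the lowest normalized signal among probes well above background and the dim probe's own. The 23 fixed lists (387 genes) and 15 families, matched by words in the gene descriptions with letter case ignored, were tested with camera at its preset inter-gene correlation of 0.01, for sets with at least 5 measured members; an estimated correlation and fry were alternatives. Genes with a missing value on an array were left out of set tests. Means of the cell type lists per array were compared with an exact two-sided permutation test over the 35 splits (scipy 1.17.1). Its two-sided p doubles the smaller tail, so with these splits it cannot go under 0.0571; the plan had put its minimum at 1 of 35 splits by mistake. A p from absolute differences, added after the data were seen, can reach 0.0286.

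Named genes follow a rule set before the data were examined: the 10 largest rises and 10 largest falls among called genes with a symbol, groups that do not overlap and a probe well above background on all 7 arrays; of each list, up to 4 called members per direction, and a fixed set of guard cell and reference genes whether called or not; and up to 5 genes per direction detected in 1 group only. Gene lists, tests and most alternatives were also set then. The alternatives were quantile and median scaling, a percentile over detected probes, the authors' series table, other filters, other rules for several probes, a trended robust prior, array weights, other thresholds, leaving out each array, and replicate number as a block. Normexp on mean signals could not be run, since that column is not in the tetraploid Col files used here. Added after the data were seen were normexp on median signals, alone or with an estimated correlation, and centring on the reference genes. So were counts over genes with several probes, letter case kept in family words and a p from absolute differences. Normexp was run with an offset of 50 added to every signal, which by itself shrinks the folds of dim genes. The fit was tested on simulated data with this comparison's 20216 gene means and spreads: of 100 genes changed by a log2 of 1.5, 70.0% were recovered, of 100 changed by 3, 93.0%, with 6 calls among unchanged genes. A common gene name is used where the gene table holds another, such as MAM3 for IMS2. Figures were drawn with matplotlib 3.10.9.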

Results

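Transcript levels were measured in guard cell protoplasts, the wall-less cells of the leaf's stomatal pores, from 2 tetraploid lines of Arabidopsis thaliana: the accession Me-0 (n = 4 arrays) and tetraploid Col (n = 3 arrays), a line of the reference background with the same ploidy. The arrays carried 43603 non-control probes for 26060 genes. Between 31130 and 32832 probes per array were well above background. The design asks which transcripts differ between guard cells of the 2 lines.

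Me-0 and tetraploid Col guard cells differed in the level of many transcripts. Of 20216 genes tested, 2046 were higher and 1841 lower in Me-0 by at least 2-fold at an adjusted p below 0.05 (limma). CYP709B2 (AT2G46950), a cytochrome P450, was 104-fold higher in Me-0, and MAM3 (AT5G23020), a chain-elongating synthase of glucosinolate production, was 20.9-fold higher. LpxC2 (AT1G24880) was 602-fold lower and CYP89A5 (AT1G64950), another P450, 293-fold lower. The folds with normexp on median signals were 28.2 for CYP709B2, 144 for LpxC2 and 132 for CYP89A5. Arrays correlated with r of 0.984 to 0.992 across genes within Me-0, 0.980 to 0.993 within tetraploid Col and 0.906 to 0.919 between them, and the first principal component held 79.9% of the variance. In 46.8% of genes the groups did not overlap, where chance gives 5.71%. Among called genes with several probes, all probes were called alike for 268 of 483 rises and 236 of 387 falls, and some probe was called the other way for 20 and 7. Starting from any probe that changed at least 4-fold, another probe of the gene failed to follow by 2-fold in 171 of 304 genes with falls and 36 of 136 with rises. For any gene called lower, a Me-0 sequence that differs at the probe was not excluded, so its transcript level need not be lower. Each group was hybridised on a slide of its own, so line and slide cannot be told apart. The counts were 1027 and 726 with normexp on median signals, 4364 and 3746 with no fold minimum, and 2162 and 4964 with no filter on dim probes. More genes were lower than higher, unlike above, also when centred on the reference genes (1718 higher, 2090 lower), without tetraploid Col replicate 1 (1654 and 1885), at an adjusted p below 0.01 (1534 and 1559), with every probe tested (2285 and 2410) and over genes with several probes when any probe counted (712 and 944), and quantile normalization gave 2387 and 1691.

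**Figure D1:**
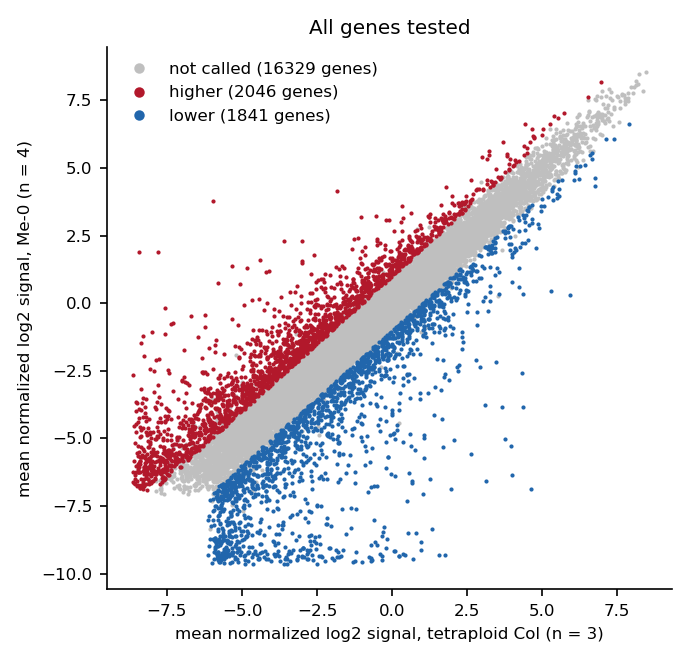
Mean normalized log2 signal of each gene in tetraploid Col (x axis, n = 3) and Me-0 (y axis, n = 4), with the array's 75th percentile at 0. Red points are the 2046 genes called higher in Me-0, blue points the 1841 called lower, grey points genes not called.

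The largest rises by the fixed rule were CYP709B2 (log2 difference 6.70 ± 0.29 SE), IGMT3 (4.55), an indole glucosinolate methyltransferase, MAM3 (4.39), LTP3 (4.20), a lipid transfer protein, MRD1 (4.03), ORS1 (3.76), ESP (3.76), DAA1 (3.73), ACX5 (3.64), an acyl-CoA oxidase, and RLP43 (3.63). The CYP709B2 probe lies on chromosome 2 at 19289763 to 19289822 (TAIR10, as in the array files). ACX5 rests on 1 of its 2 probes: the other gave -0.11, the mean of both 1.77, and that probe was the brighter one without any single Me-0 array, where the difference was -0.13 to -0.08 and not called. The largest falls were LpxC2 (-9.23 ± 0.24 SE), an enzyme of lipid A synthesis whose probe lies on chromosome 1 at 8777871 to 8777930, CYP89A5 (-8.19), CYP81G1 (-7.28), QQS (-7.02), a regulator of starch content, CYP72A11 (-6.84), PLC8 (-6.22), EM6 (-5.92), RLP52 (-5.90), UGT73B4 (-5.64) and TTN10 (-5.57). All adjusted p-values of these 20 genes lay at or below 0.0032 (limma). With normexp on median signals the fold was smaller by over 1.5 times for 9 of these falls and 6 rises. As log2 differences, the falls were LpxC2 (-7.17), CYP89A5 (-7.05), QQS (-5.09), CYP81G1 (-4.33), PLC8 (-3.91), CYP72A11 (-3.88), EM6 (-3.84), TTN10 (-3.31) and RLP52 (-3.28). The rises were CYP709B2 (4.82), IGMT3 (3.83), LTP3 (3.07), MRD1 (2.99), DAA1 (2.75) and RLP43 (2.35). All 15 were still called.

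Among 18 measured guard cell identity genes, 3 rose and 1 fell. ALMT12 (AT4G17970), the anion channel of stomatal closure, was 6.48-fold higher in Me-0 (3.32 ± 0.76, n = 4, against 0.62 ± 0.44, n = 3; adjusted p = 0.0020, limma). EPF1 (AT2G20875), a peptide that spaces stomata, rose by a log2 of 2.22, and MYB60 (AT1G08810), a guard cell transcription factor, by 1.19, with its second probe at 1.18. TGG2 (AT5G25980), a myrosinase, was 6.23-fold lower (-2.64), while its relative TGG1 stood at 0.30 and was not called. The TGG2 value rests on 1 tested probe, where a differing Me-0 sequence was not excluded. SLAC1, the main slow anion channel, differed by 0.05 ± 0.13 SE (adjusted p = 0.80), a value whose sign changed with centring on the reference genes (-0.05). KAT1 (0.61), GORK (0.60), HT1 (0.66), BLUS1 (0.55), OST1 (-0.46), KAT2 (-0.73) and ABCB14 (2.14-fold higher, adjusted p = 0.118) were not called. Of these, HT1 (adjusted p = 0.014), OST1 (0.045) and KAT2 (0.0080) missed only the 2-fold minimum (limma). ABCB14 passed without Me-0 replicate 3 (1.48), and 1 of the 3 OST1 probes gave -1.61. The median of this list was 0.57, that of the mesophyll markers -0.88 and that of the epidermal markers 0.69.

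**Figure D2:**
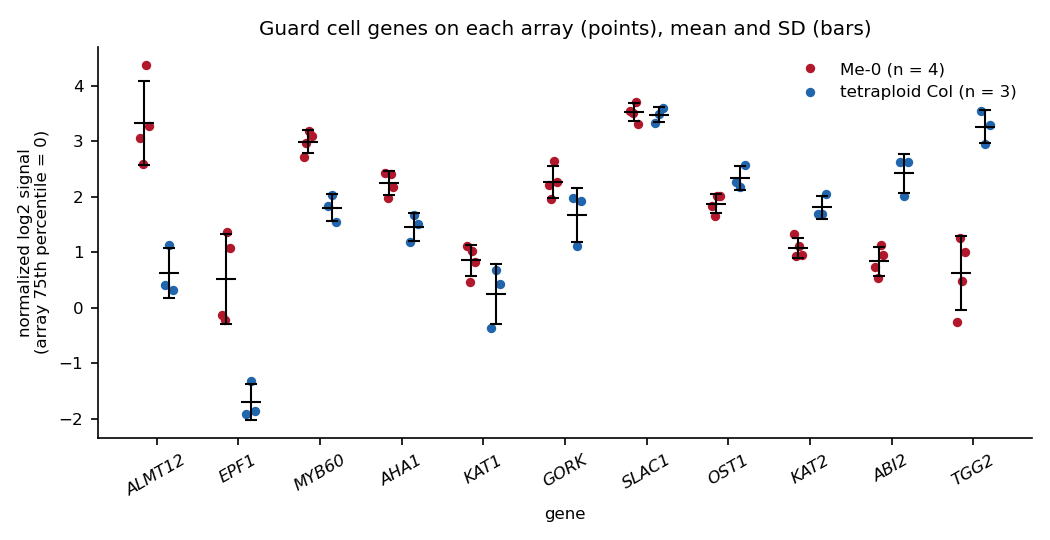
Normalized log2 signal of 11 guard cell genes on each array (points; red Me-0, n = 4; blue tetraploid Col, n = 3) with group mean and SD (bars). ALMT12, EPF1 and MYB60 lie higher in every Me-0 array, TGG2 and ABI2 lower, and SLAC1 overlaps.

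Of 33 measured ion transport genes 3 rose and 1 fell: besides ALMT12, KUP8 (1.51) and ALMT6 (1.41) rose, and CHX20, a cation/proton exchanger of guard cells, fell (-1.02). CHX20 lost its call without Me-0 replicate 3 (-0.94) or 4 (-0.99) or tetraploid Col replicate 3 (-0.91), and with quantile (-0.97) or median scaling (-0.98) or the authors' series table (-0.97). The plasma membrane proton pumps AHA1 (0.79), AHA2 (0.20) and AHA5 (0.24) and the transporter ABCC5 (0.11) were not called. Of these, AHA1 missed only the 2-fold minimum (adjusted p = 0.0088, limma), and the lowest of its 3 probes gave 0.0077. Of 18 stomatal development genes 2 rose, EPF1 and SDD1 (2.04), a subtilisin-like protease, and 0 fell. Of 15 genes of light and stomatal opening 2 rose, TSF and SOC1, and 0 fell; the phototropins PHOT1 (-0.24, its other probe -1.73) and PHOT2 (0.52) were not called. With normexp on median signals SDD1 (0.95) and TSF (1.53) were not called. In the carbon dioxide list of 12, CBC1, a kinase, rose (1.83) and the carbonic anhydrase CA1 fell (-1.11). CBC1 was not called without tetraploid Col replicate 1 (1.61) or 3 (1.66), nor CA1 without Me-0 replicate 1 (-0.99) or with array weights (-0.92) or normexp on median signals (-0.97).

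Genes of abscisic acid, the hormone that closes stomata, went both ways. Of 25 measured perception and signalling genes 1 rose, the receptor PYR1 (1.02), and 2 fell, the receptor PYL3 (-3.04, well above background on 1 of the 4 Me-0 arrays) and ABI2 (-1.58 ± 0.21 SE; 2.99-fold; adjusted p = 0.0010), a phosphatase that holds the pathway off. ABI2 rests on 1 tested probe, where a differing Me-0 sequence was not excluded. PYR1 was not called without Me-0 replicate 2 (0.99) or tetraploid Col replicate 1 (0.86). ABI1 (-0.42), HAB1 (-0.39), PYL4 (-0.25), PYL5 (0.30) and PYL8 (0.55) were not called, of which ABI1 (adjusted p = 0.049) and PYL8 (0.035) missed only the 2-fold minimum (limma). Of 14 metabolism and transport genes 2 rose and 2 fell: ABA2 (1.49), a biosynthetic dehydrogenase, and CYP707A1 (1.02), which degrades the hormone, rose, and CYP707A4 (-4.79, well above background on 3 of the 4 Me-0 arrays) and NCED2 (-3.08) fell. CYP707A1 was not called without Me-0 replicate 1 (0.97) or tetraploid Col replicate 1 (0.82), and its other probe gave 0.71. NCED3 (-0.46), CYP707A3 (0.63) and the importer ABCG40 (-0.02) were not called. CYP707A3 missed only the 2-fold minimum (adjusted p = 0.021, limma), and the lowest of its 3 probes gave -0.14. Of 19 responsive genes 3 rose, RD22 (1.86), ATHB7 (1.84) and RAB18 (1.70), and 3 fell, EM6 (-5.92; 60.7-fold), LTI30 (-4.83; 28.4-fold) and RD29B (-2.18, well above background on 3 of the 4 Me-0 arrays); RD29A stood at -0.17. RAB18 lost its call without Me-0 replicate 1, 3 or 4 or tetraploid Col replicate 1 or 3 (1.33 to 1.83), and RD29B without Me-0 replicate 1 (-2.19) or tetraploid Col replicate 1 (-1.84) or 3 (-2.20). With normexp on median signals PYL3 (-0.35), CYP707A4 (-1.66), RD29B (-0.21), RAB18 (1.64), CYP707A1 (0.79) and PYR1 (0.90) were not called, and EM6 (-3.84) and NCED2 (-1.99) were smaller. CYP707A4 stood at -4.19 without Me-0 replicate 4. Centred on the reference genes, or with the percentile over detected probes, CYP707A1 (0.92 and 0.99), PYR1 (0.92 and 0.99) and RAB18 (1.61 and 1.68) were not called either, nor was CYP707A1 with the mean of its probes (0.86) or PYR1 with array weights (0.98).

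Of 15 measured flowering genes 5 rose and 3 fell. The florigen relative TSF (4.10, well above background on 1 of the 3 tetraploid Col arrays), AP1 (2.73, on 2 of the 3), MAF3 (2.50) and SOC1 (1.89) rose, while the repressor FLC (AT5G10140) was 6.60-fold lower (-2.72), and MAF4 (-3.48) and MAF5 (-1.84; its other probe -0.66) fell too. FT stood at 3.31 ± 1.52 SE and was not called (adjusted p = 0.120), with 2 of the 3 tetraploid Col arrays well above background; it passed without tetraploid Col replicate 2 (5.37) and with array weights (4.10). TSF lost its call without tetraploid Col replicate 1 (3.45) or 3 (3.55), as did FLC (-2.00 and -2.05), and MAF5 without tetraploid Col replicate 1 (-1.06). With normexp on median signals TSF (1.53), FLC (-1.26), MAF4 (-1.51) and MAF5 (-0.52) were not called, and AP1 (1.31) was smaller. TSF was larger without tetraploid Col replicate 2 (5.32) or Me-0 replicate 4 (4.73) and with array weights (5.04), and FLC without tetraploid Col replicate 2 (-3.31); the mean of the MAF5 probes was -1.25. Of 15 clock genes 0 rose and 1 fell, RVE1 (-1.04; its other probe -0.37), which was not called without Me-0 replicate 3 (-0.92) or tetraploid Col replicate 3 (-0.85), with the authors' series table (-0.37) or with the mean of its probes (-0.71). Of 15 cell cycle genes 3 rose and 0 fell: the inhibitors KRP2 (2.56 ± 0.36 SE) and SIM (1.03), and CDKB1;2 (1.15), whose other probe gave -0.68. SIM was not called without Me-0 replicate 4 (0.99) or tetraploid Col replicate 1 (0.94) or 3 (0.93), with normexp on median signals (0.83), centred on the reference genes (0.94) or with the mean of its probes (0.89), nor CDKB1;2 without tetraploid Col replicate 1 (0.94) or with the mean of its probes (0.23).

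Of 24 measured genes of glucosinolates, defence compounds split by myrosinases, 5 rose and 5 fell. ESP (AT1G54040), which turns the breakdown towards nitriles, was 13.5-fold higher (3.76), and ESM1 (-6.26), which acts the other way, was lower and well above background on 2 of the 4 Me-0 arrays. MAM3 (4.39), CYP79F1 (1.43) and SOT17 (1.06) rose too. MYB29 (at least 10.3-fold lower; not well above background in Me-0), TGG2 and GS-OX3 (-2.09) fell. SOT17 was not called without Me-0 replicate 3 (0.93) or tetraploid Col replicate 1 (0.99) or 3 (0.82) or centred on the reference genes (0.96). Of the 2 CYP79F1 probes 1 gave 0.14, and with their mean (0.78) the gene was not called. With normexp on median signals MYB29 (-0.57) and GS-OX3 were not called, and ESM1 (-3.06) was smaller. ESP stood at 3.13 without Me-0 replicate 4.

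Of 18 measured jasmonate genes 1 rose, the repressor JAZ7 (1.57), and 4 fell: LOX2 (-1.92), CORI3 (-1.74), TAT3 (-1.43) and JAR1 (-1.16). CORI3 was not called without tetraploid Col replicate 1 (-1.52) or 3 (-1.64) or with normexp on median signals (-1.12). With replicate number as a block, LOX2 (-1.82) and CORI3 (-1.76) were not called. Of 19 salicylate and defence genes 2 rose, NIMIN1 (2.03) and PNP-A (1.80), and 2 fell, the defensin PDF1.2A (-3.55) and CBP60G (-1.24). PDF1.2A, well above background on 3 of the 4 Me-0 arrays, lost its call without Me-0 replicate 3 or 4 or tetraploid Col replicate 2 or 3 (-3.66 to -3.08) and with normexp on median signals (-1.52), and ran from -4.32 to -2.77 without 1 array. Of 12 wounding and touch genes ERF6 fell (-2.04) and 0 rose. Of 14 heat shock genes the small chaperones HSP18.2 (-2.93) and HSP21 (-1.65) fell and 0 rose. Of 23 calcium and reactive oxygen genes CPK21 rose (1.41) and CPK23 (-3.28), CAS (-1.34) and CPK11 (-1.03) fell; the oxidases RBOHD (-0.17) and RBOHF (-0.35) were not called. CPK11 was not called without Me-0 replicate 3 (-0.97) or with normexp on median signals (-0.96), where CPK23 was smaller (-2.05).

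Of 16 mesophyll and photosynthesis genes 1 was called higher and 3 fell: RBCS1B (-2.01), LHCB1.1 (-1.62) and CA2 (-1.01) fell, and LHCB2.1 (1.41) rose on the probe used, while its second probe gave -6.15. Near-identical copies share these families, so single members are uncertain. Of 12 epidermis and cuticle genes 3 rose, CER1 (2.47), CER6 (1.52) and FDH (1.01), and of 10 vascular and trichome genes 2, SUC2 (1.55) and FTIP1 (1.03); 0 fell in both lists. CA2 was not called without Me-0 replicate 1 (-0.98) or 3 (-0.87) or tetraploid Col replicate 1 (-0.87), FDH without Me-0 replicate 2 (0.92) or 4 (0.95) or tetraploid Col replicate 3 (0.98), and FTIP1 without Me-0 replicate 1 (0.95) or tetraploid Col replicate 1 (0.80) or 3 (0.94). CA2 was not called either with normexp on median signals (-0.97), median scaling (-0.97) or array weights (-0.90), nor FDH centred on the reference genes (0.92) or with the percentile over detected probes (0.99), nor FTIP1 centred on the reference genes (0.94), and CER1 was smaller with normexp (1.85). Per array, the mesophyll mean was 2.99 ± 0.30 in Me-0 (n = 4) and 3.66 ± 0.28 in tetraploid Col (n = 3), the epidermal mean 1.57 ± 0.50 and 0.77 ± 0.28 (each exact permutation p = 0.0571, two-sided, the smallest scipy's test can give with these splits; adjusted 0.114 over 4 lists). The guard cell (0.31; exact p = 0.171) and vascular (0.40; exact p = 0.229) means differed by less than that.

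Of 17 starch, sugar and malate genes 2 rose, the hexose carrier STP4 (1.41) and PPC2 (1.13), and 2 fell, APL1 (-1.70) and the amylase BAM1 (-1.53). Of 16 aquaporins 0 rose and 3 fell, TIP2;1 (-1.76), TIP1;1 (-1.20) and PIP2;6 (-1.14). PPC2 lost its call without any single array other than Me-0 replicate 2 and tetraploid Col replicate 2 (0.94 to 1.24). TIP1;1 (-1.19 to -1.02) and PIP2;6 (-1.18 to -0.86) lost theirs without any other than Me-0 replicate 4 and tetraploid Col replicate 2, and TIP2;1 without any other than Me-0 replicate 4 (-1.88 to -1.26). PPC2 was not called either centred on the reference genes (1.04), with the percentile over detected probes (1.11), array weights (0.89) or the mean of its probes (0.97). With normexp on median signals TIP2;1 (-1.78), TIP1;1 (-1.17) and PIP2;6 (-1.27) were not called, nor with the mean of its probes TIP1;1 (-0.99) or TIP2;1. TIP2;1 also lost its call with quantile scaling (-1.76) or the percentile over detected probes (-1.79), and PIP2;6 with median scaling. Of 12 reference genes 0 were called. ACT2 stood at -0.48 (adjusted p = 0.0079) and UBQ10 at -0.52 (adjusted p = 0.0068, limma), so both missed only the 2-fold minimum. The mean of the 7 UBQ10 probes gave 0.12.

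**Figure D3:**
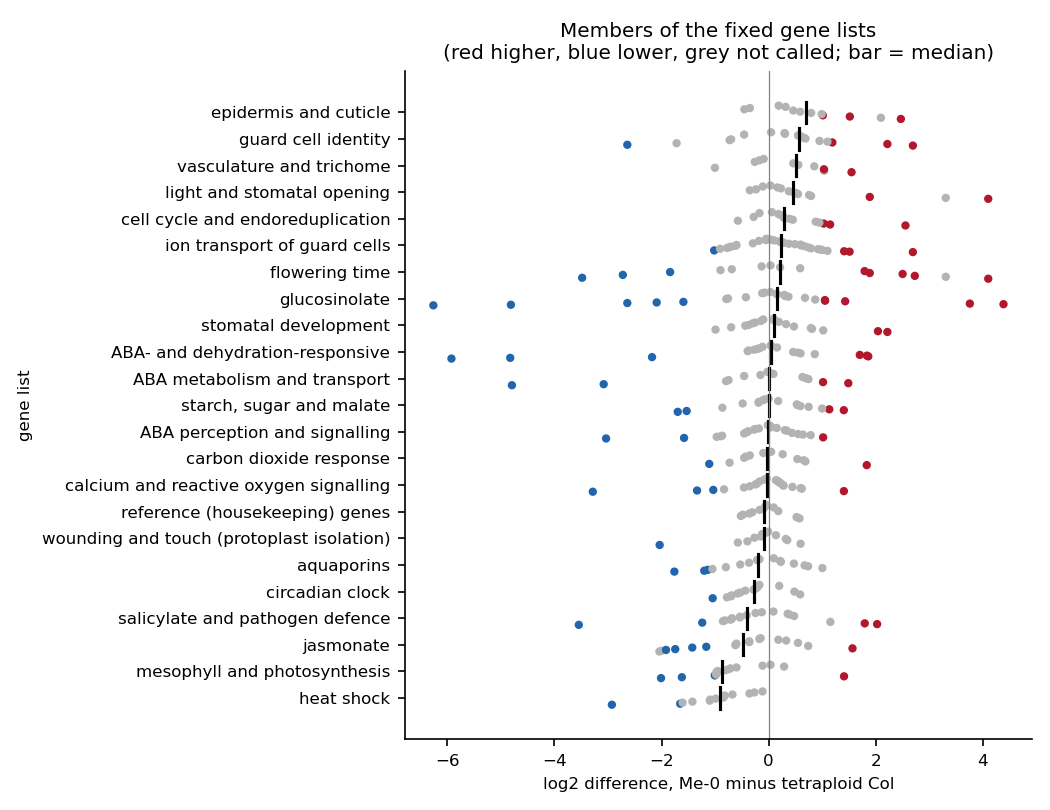
Log2 difference, Me-0 minus tetraploid Col, of every measured member of the 23 fixed gene lists (points; red higher, blue lower, grey not called), with each list's median as a bar. Medians run from -0.92 for heat shock to 0.69 for epidermis and cuticle.

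As whole sets, 0 of the 23 lists passed camera after adjustment, though the mesophyll and heat shock lists passed with quantile normalization (each adjusted p = 0.0362), median scaling (each 0.0440) or the authors' series table or only probes well above background on all arrays (each 0.0333), and the mesophyll list with the mean of a gene's probes (0.0016). In all, 6 passed with normexp on median signals: mesophyll (adjusted p = 0.0010), heat shock (0.00088), jasmonate and the clock (each 0.0212) as lower, and the cell cycle (0.0344) and epidermis (0.0411) as higher; with an estimated correlation as well, 0 did (each adjusted p of these 6 = 0.886). At an unadjusted p below 0.05 there were 4: mesophyll (median -0.88, adjusted p = 0.0553), heat shock (-0.92, adjusted p = 0.0553), epidermis (0.69, adjusted p = 0.113) and the clock (-0.28, adjusted p = 0.213). Without Me-0 replicate 3 the mesophyll (adjusted p = 0.0370), heat shock and epidermal (each 0.0284) lists passed, without tetraploid Col replicate 2 the mesophyll (0.0339) and heat shock (1.4e-05) lists, and without Me-0 replicate 2 the mesophyll list (0.0169). With an estimated correlation 0 lists had an unadjusted p below 0.05, and fry called 0, with a lowest adjusted p of 0.0543. Adjusted over the list alone, the counts of called members matched those above except for 4 rises in the epidermal list and 0 falls among aquaporins. Median and mean differed in sign for the dehydration-responsive (0.04 and -0.33), metabolism and transport (0.00 and -0.38), carbon dioxide (-0.03 and 0.07) and glucosinolate (0.15 and -0.20) lists, and the test pointed down for all 4.

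Genes described by the words disease resistance or NBS-LRR gave lower signals in Me-0 as a family: 7 of 129 rose and 53 fell, with a median of -0.63 (camera adjusted p = 7.9e-09). NBS-LRR proteins are receptors of pathogen effectors, but the word match also took in other proteins, such as the dirigent-like DIR5, which rose. The call of the family was lost with an estimated correlation (camera adjusted p = 0.963). Genes absent in Me-0, or with a Me-0 sequence that differs at the probe, would also give lower signals. Neither was checked for this family, so lower transcript levels are not established. The other 13 families tested did not pass camera, though with normexp on median signals the chlorophyll or photosystem family passed as lower (adjusted p = 0.0186, or 0.997 with an estimated correlation): their medians ran from -0.20 for chlorophyll or photosystem proteins, of which 4 rose and 3 fell, to 0.24 for cell wall loosening proteins, of which 34 rose and 21 fell. Of 732 protein kinases 70 rose and 51 fell, and of 148 cytochromes P450 28 rose and 28 fell. Rises and falls were 31 and 45 of 311 F-box genes, 14 and 17 of 351 ribosomal proteins, 3 and 4 of 49 histones, 8 and 7 of 54 glutathione S-transferases, 8 and 8 of 61 WRKY factors, 12 and 14 of 121 MYB factors, 1 and 6 of 28 aquaporins, 12 and 10 of 63 peroxidases and 0 and 0 of 59 proteasome subunits. Adjusted over the list alone, the counts differed for F-box (32), kinase (67) and cell wall (35) rises and for P450 (29), peroxidase (12) and aquaporin (3) falls. Median and mean differed in sign for P450 (0.05 and -0.12), aquaporin (0.15 and -0.33), MYB (0.11 and -0.01), peroxidase (-0.15 and 0.07) and proteasome (0.01 and -0.01) genes. By fry, which sets a family against no change and not against other genes, the disease resistance, F-box and glutathione S-transferase families passed as lower (each adjusted p = 0.000718), with 154 F-box members above 0 and 157 below, and 26 and 28 glutathione S-transferases. The transposable element family had 1 measured member and was not tested.

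Detected in Me-0 only were 451 genes, and in tetraploid Col only 264. Among those with a gene symbol, highest in bound were WRKY59 (at least 52.5-fold higher in Me-0), the transcription factor NAC025 (at least 36.7-fold), BST1 (at least 32.2-fold), DIR5 (at least 20.4-fold) and SHP1 (at least 9.91-fold). In the other direction, again among genes with a symbol, stood the immune receptor WRR4 (at least 313-fold lower in Me-0), ACC1, an acetyl-CoA carboxylase (at least 215-fold), SEH (at least 145-fold), the actin-related ARPC4 (at least 139-fold) and TBL23 (at least 122-fold). These bounds hold for the processed signal, and with normexp on median signals they were far lower: 9.09-fold for WRKY59, 5.71 for NAC025, 5.72 for BST1, 4.51 for DIR5 and 3.41 for SHP1, and 23.3-fold for WRR4, 14.2 for ACC1, 11.3 for SEH, 11.7 for ARPC4 and 9.38 for TBL23. The normexp offset of 50 by itself shrinks folds that rest on such dim signals. By the positive-and-significant flag of the files the counts were 295 and 690. The lowest normalized signal among probes well above background was -7.6 to -7.2 on the Me-0 arrays and -6.4 to -6.3 on the tetraploid Col arrays. A gene at the same level in both lines could therefore count as detected in Me-0 only. The excess of 451 over 264 thus need not be a difference between the lines. Of the genes named here, BST1, DIR5, SHP1, ACC1, SEH, ARPC4 and TBL23 each rest on 1 tested probe. For the genes lower in Me-0, a Me-0 sequence that differs at the probe was not excluded, so a lower signal need not be a lower transcript level.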

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

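The tests of a response to brightness, of the signal floor, of probes starting from any changed probe, of second probes of the 16-fold falls, and of the guard cell share were chosen after the results they weigh were seen. In 10 of 137 results tested, 1 Me-0 array stood apart from the other 3 (7.30%; chance gives about 1 in 20). The ratio of the gap to the range was 0.971 for HT1, 0.964 for BAM1, 0.921 for TTN10, 0.906 for CYP707A4, 0.885 for BST1, 0.875 for HSP18.2, 0.865 for SOC1, 0.857 for ARPC4, 0.843 for SHP1 and 0.835 for MYB29. Me-0 replicate 3 was the array apart in 5 of them. Among probes with no single locus, which no gene count includes, 555 were higher and 777 lower in Me-0 of 3910 tested.

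The first pattern is the size of the difference: 3887 genes called. Of the 35 splits of the 7 arrays, 1, the real one, called as many, and the highest of the others called 3. Chance in the grouping of these arrays is thus unlikely, though 1 of 35 is the least this test can give. The real split is also the split by slide, which the test cannot tell from line. Chance differences between plantings or isolations are not excluded if the replicates are technical. Quantile normalization, which removes any response that keeps the order of the probes on an array, kept 95.4% of the calls in the same direction (3709 genes), which argues against a signal response to brightness alone as the whole cause. Other effects of the scanners, scan passes and software remain open. Of 8 spike-in probes well above background on all arrays, the largest difference beyond the common shift was 0.802 (absolute log2). This lay between the bounds set beforehand and came from the dimmest probe, 3.68 in Me-0 and 4.82 in tetraploid Col. Before the common shift of -0.33 was removed, its unscaled difference was -1.13 ± 0.07 SE, lower in Me-0 by over 2-fold. The other probes lay between -0.24 and 0.56 beyond the shift. Normexp on median signals kept 43.0% of the calls, but its offset of 50 alone shrinks dim folds, so this share cannot weigh the scanners. The day of growth, isolation, labelling or hybridization cannot be told apart from the line, since 0 slides hold both groups, and the difference of line that the design names stays open as well, untested against these.

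The second pattern is that 265 falls but 76 rises reached 16-fold among called genes, by fitted values that for dim genes are no bounds; with normexp on median signals they were 38 and 13. With every array raised to 1 common floor, the highest of the 7, there were 139 falls and 44 rises (ratio 3.16, 95% interval 2.24 to 4.54), which argues against the lower signal floor of the Me-0 arrays as the whole cause; a ratio of 3.57 among genes well above background on all arrays decides nothing, since the lower Me-0 floor leaves falls more room there. Of the 265 falls, 47 had a second detected probe elsewhere, which fell by 2-fold or more in 45 and by 16-fold in 32, so that 31.9% stayed short of 16-fold (exact 95% interval 19.1% to 47.1%; rises 6 of 12), between the bounds set for it, and a sequence difference at 1 probe site stays open for the falls as a whole, 218 of which had no such probe. At 4-fold, a second probe failed to follow the brightest one by 2-fold in 10.3% of falls and 16.9% of rises (-6.57 percentage points), inside the bound set beforehand, but that bound was wrong because the brightest probe over all arrays passes over probes dimmed in Me-0: from any changed probe, another failed to follow in 56.2% of 304 genes with falls and 26.5% of 136 with rises (29.8 percentage points; Fisher's exact p = 5.5e-09). This gap met the prediction for sequence differences at single probe sites, which was written after earlier values were seen. It covers changes of at least 4-fold at any probe, so such differences stay open for the 16-fold falls. Genes absent or diverged along their whole length in Me-0 would carry all probes down, and they stay open because no Me-0 genome was used here.

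The third pattern is the lower mesophyll markers beside higher epidermal ones. A different share of guard cells alone would move markers of other cell types the same way. The list medians were -0.88 ± 0.14 for mesophyll, 0.69 ± 0.28 for epidermis and 0.51 ± 0.35 for vasculature (each a bootstrap SE). Guard cells are themselves epidermal, so the epidermal list cannot serve as one of other cell types. The guard cell list had a median of 0.57, with 13 of its 18 members above 0. The mesophyll and vascular medians lay on opposite sides of 0 by more than their SEs, which met the rule written against a different share of guard cells. The vascular median lay little beyond its SE, however, so a different share of guard cells stays open. Fewer mesophyll cells in the Me-0 preparations remain open (13 of the 16 markers lay below 0, from -2.01 for RBCS1B to 1.41 for LHCB2.1): the chlorophyll or photosystem family of 70 genes had a median of -0.20 ± 0.07 (bootstrap SE), too near the bound set beforehand to exclude it. Regulation of photosynthesis genes within guard cells was not tested.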

How the results depend on the processing

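Normexp on median signals (alone or with an estimated correlation), centring on the reference genes, the counts over genes with several probes and the case-kept family words were chosen after the data were seen. Over single genes, 2432 values under alternatives held 2275 on the same side of the threshold and in the same direction, 134 no longer past it, 3 newly past it and 20 of the other sign. Where a result below differs from the report, the cause was not tested unless stated. Normexp on median signals gave 1027 genes higher and 726 lower, with 1670 called in the same direction as reported, a median of all genes of 0.11 against 0.05, 6 lists and 2 families. Of 129 named genes, 43 moved by over 1.5 times in fold, and 83 of the 100 called ones were smaller. The normexp offset of 50 by itself shrinks the folds of dim genes, and how much of these changes it makes was not tested. With no filter on dim probes 4964 genes were lower, over 26060 genes tested. Counted over genes with 2 or more probes, which are fewer, 269 were higher and 237 lower with all probes called alike, and 712 and 944 with any probe called. With no fold minimum, a looser threshold by construction, the counts were 4364 and 3746. The lists passing camera were 2 with quantile normalization, median scaling, the series table or only probes well above background on all arrays, 1 with the mean of a gene's probes, 1 with replicate number as a block and 0 to 3 without 1 array. Families passing were 0 with an estimated correlation, and 0 with that and normexp on median signals. By the positive-and-significant flag 295 genes were detected in Me-0 only and 690 in tetraploid Col only.

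The sign changed for SLAC1 with centring on the reference genes (-0.0475), array weights (-0.0220) and without 1 array (-0.0233 to 0.116), and for ABCG40 with median scaling (0.0107), the replicate block (0.0154) and without 1 array (-0.181 to 0.0757). It changed with the mean of a gene's probes for UBQ10 (0.12), TGG1 (-0.0399) and LHCB2.1 (-2.37), where averaging brings in probes that differ. Without 1 array AHA2 ran from -0.0142 to 0.390, PHOT1 from -0.409 to 0.0705 and ACX5 from -0.13 to 3.71; ACX5 stood at -0.13 under the replicate block, where its other probe is the brighter. The replicate block called 1927 genes higher and 1847 lower, against 2016 and 1873 in the same arrays without it. Named genes that lost their call under the block were LOX2 (-1.82), CORI3 (-1.76), CBC1 (1.71), RAB18 (1.67), PIP2;6 (-1.39), SOT17 (1.11), CHX20 (-0.99), SIM (0.99), PPC2 (0.95) and FDH (0.95). Deviations of same-numbered arrays correlated at -0.04, 0.09 and -0.09, and not every array correlated best with its own number. These values show no pairing by number, but they cannot exclude that a number marks a shared planting or isolation. Normexp on mean signals and a slide block were not run, the first for want of the column in the files used here and the second because each slide holds 1 group. Signal over background limits the fold of dim genes: only those not well above background on any array of a group are given as a bound, and for genes detected on some arrays of a group the difference rests partly on signals near background.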

Other observations

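The Fisher's exact tests here were chosen after the data were seen, and genes are not independent replicates. Families differed in how many members were called in either direction, against 19.2% of all genes. Called were 46.5% of disease resistance genes (60 of 129; adjusted p = 4.0e-11), 37.8% of cytochromes P450 (56 of 148; adjusted p = 7.3e-07), 36.2% of cell wall loosening genes (55 of 152; adjusted p = 3.0e-06) and 34.9% of peroxidases (22 of 63; adjusted p = 0.0084). Ribosomal proteins (8.83%, 31 of 351; adjusted p = 5.8e-07) and proteasome subunits (0 of 59; adjusted p = 1.9e-05) were called less often.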
